A study of Mus musculus with 8 samples.

How the data were processed

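RNA of lymphatic endothelial cells sorted from mouse ear skin was measured on 8 single-colour oligonucleotide arrays, 4 from untreated skin and 4 from skin with contact hypersensitivity. Per the labels' protocols, total RNA of the sorted cells was amplified by linear isothermal amplification into single-stranded cDNA, which was fragmented, labelled with biotin and hybridised. The deposited table holds 1 intensity value per probe set and array on a linear scale, and the values are MAS5 signals per the submitters' processing notes. The version of MAS5, its scaling target and any detection filter are not given in the sources used here, and detection calls were not used here. The table listed 45101 probe sets, of which 64 were AFFX controls. No 2 arrays held identical values. Of the other 45037 probe sets, 34945 named 1 gene in GEO's platform annotation, 932 named several and 9160 had no gene there. No gene was named from a probe set with several genes or none. The gene IDs of 34741 of the 34945 probe sets were found in the RefSeq gene table of the mouse, and no symbol needed updating. Of the 981 entries of 43 gene lists, 915 were measured by a probe set naming that gene alone.

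Array medians of log2 signal differed by at most 0.468, under the limit of 0.5 set for further normalization, so the authors' scaling was kept and no pseudocount was added. Probe sets with a mean log2 signal under the median of all probe sets (3.30, a signal of 9.84) were left out. Of the probe sets naming 1 gene, the one with the highest mean represented the gene, which left 10843 genes. Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with the pair as a fixed block and the Benjamini-Hochberg adjustment over all genes at a threshold of 0.05. Adjusted p-values in the text are from this fit unless another test is named. A change is the mean log2 signal of inflamed minus untreated arrays, averaged over 4 pairs. Its standard error (SE) is the moderated one of the limma fit. It is drawn towards that of genes of like intensity and does not give the spread of the 4 pairs alone. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 39 lists with at least 5 tested members, and beside it with an estimated correlation, which no list passed, and with fry. Means of lists and array measures were compared by an exact two-sided sign-flip permutation over the 4 pairs, which 4 pairs cannot bring under 0.05.

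The pairing comes from the series' design text, which states that each pair of 1 control and 1 inflamed sample was sorted and extracted on the same day, and same-numbered samples have the same age. The numbers as such were checked against the values across genes, which are not independent replicates: deviations from the group means correlated at 0.16, 0.00, 0.08 and 0.03 within pairs 1 to 4, so the values alone carry little sign of the pairing. Each sample was pooled from 3 mice, so p-values refer to pools and not to single mice. They rest on the spread of the differences within pairs, with 3 residual degrees of freedom. This spread was moderated by that of genes of like intensity, with a median of 6.27 prior degrees of freedom.

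Because no detection calls were used, a background ceiling was set per array as the 95th percentile of the bacterial control probe sets that are not spiked into the hybridisation mix. This rule was chosen after the values were seen. A gene at or under the ceiling on every array of a group has only a bound there, written as "at least N-fold": the mean of the brighter group against the mean ceiling of the dimmer. The ceilings lay between 2.53 and 3.31 on the log2 scale, signals of 5.79 to 9.94. The number of arrays limits the precision. On simulated data of 10843 genes built from this comparison's spread, with 200 genes changed, the fit recovered 8% of the genes changed by 1 on the log2 scale, 32% of those changed by 2, 66% by 3 and 88% by 4, and it called 6 of 10643 unchanged genes. It called 0 genes in simulated data with no change. The simulated spread was the moderated one, already drawn towards the intensity trend, with normal errors. These shares and counts therefore cannot show how far the real calls depend on that trend. Camera gave p under 0.05 for 1.5% of 200 simulated unchanged lists. The simulated genes varied independently of one another, so this share does not hold for lists whose members are correlated. Among the real lists the estimated correlation reached 0.46, for pericyte and smooth muscle markers.

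Before the data were examined, the design, the gene lists, the alternatives and the rule for naming genes were fixed. Named were the 10 genes with the largest rise and the 10 with the largest fall in measured log2 signal among those past the threshold and changed the same way in all 4 pairs, up to 4 members with the smallest p of each list described, and Pecam1, Pdpn, Ptprc, Prox1, Lyve1, Flt4, Icam1, Vcam1, Ccl21a and Cxcl12 where a probe set naming only that gene was measured and tested. Ccl21a had no such probe set and Ptprc was too dim to be tested. Genes named outside this rule are said to be so. Alternatives were the fit without the block or with a random block, quantile and cyclic loess normalization, median centring, no filter or a stricter filter at the 70th percentile, pseudocounts of 16 and 64, the mean of a gene's probe sets, no intensity trend, array weights, leaving out each pair, a test per probe set, a minimum of 2-fold, and the other list tests. An exact permutation of list means over 35 splits was added after the data were seen. Figures were drawn with matplotlib 3.10.9.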

Results

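Gene expression was measured in lymphatic endothelial cells from the ears of female FVB mice. Lymphatic endothelial cells line the vessels that drain fluid and leukocytes from tissue. They were sorted as cells carrying CD31 and podoplanin and lacking the leukocyte marker CD45. Inflamed samples came from mice sensitised with 2% oxazolone, a contact allergen, on the abdomen and paws and challenged 5 days later with 10 µl of 1% oxazolone on each ear side, and the ears were taken 24 hours after the challenge. Untreated samples came from mice described as healthy. Each group held 4 samples of 3 mice each, forming 4 pairs processed on shared days, at ages of 8 to 10 weeks. The mean signal per array lay between 126.2 and 160.4, and between 53.5% and 62.6% of probe sets were above the background ceiling. The comparison addresses how the transcripts of these cells differ between inflamed and resting skin.

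In inflamed skin, transcripts of chemokines, interferon-induced proteins and antigen presentation were higher, and several endothelial identity, Notch pathway and lipid transport transcripts were lower. The mean levels of the tested neutrophil, monocyte and fibroblast markers were higher and the 3' to 5' ratio of Gapdh was lower in all 4 pairs, so these moved along with every group of genes given below. The same ratio of Actb went both ways, higher in 2 of the 4 pairs. Of 10843 genes tested, 424 were higher and 328 lower in inflamed samples at an adjusted p under 0.05 in limma, and 423 and 327 of these moved the same way in all 4 pairs. At a minimum of 2-fold, 359 were higher and 310 lower. The split depended on scaling: median centring, which moved the median change of all genes from -0.09 to 0.22, gave 719 higher and 227 lower, or 76.0% higher against 56.4%. The count also fell to 94 higher and 47 lower without the intensity trend, where 76 of the 120 genes that had passed among those examined one by one no longer did, and to 241 and 151 without pair 1, 269 and 165 without pair 2, 194 and 103 without pair 3, and 293 and 185 without pair 4.

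Genes were ranked by the measured log2 difference, and where a group lay under background only a bound holds, so that no order can be read among such genes. Timp1, an inhibitor of matrix metalloproteinases, went from 0.66 ± 0.58 to 10.03 ± 0.87 on the log2 scale (SD, n = 4), at least 134.5-fold higher (adjusted p = 0.000115). Cxcl10, an interferon-induced chemokine for activated T cells, was at least 133.0-fold higher at 10.02 ± 0.66 against 0.69 ± 0.89. Cd53, a tetraspanin known mainly from leukocytes, was at least 128.7-fold higher. The neutrophil chemoattractants Cxcl5 and Cxcl2 were at least 71.7-fold and 16.97-fold higher. Chil3, a chitinase-like protein known from activated myeloid cells, was at least 33.0-fold higher, Arg1, the arginine-degrading enzyme arginase, at least 37.4-fold and S1pr3, a receptor for sphingosine-1-phosphate, at least 32.2-fold. None of these 8 genes was above background on any untreated array. Saa3, an acute-phase protein, rose by 7.42 ± 0.71 (SE; 1 of 4 untreated arrays above background), and Cd274, which encodes the T cell inhibitory ligand PD-L1, by 7.39 ± 0.67 (2 of 4).

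Among the 10 largest measured falls, Scn3a, a voltage-gated sodium channel subunit, went from 8.99 ± 0.68 to 1.23 ± 1.57 (SD, n = 4), at least 62.9-fold lower (adjusted p = 0.000561). Inpp4b, a phosphoinositide phosphatase, was at least 29.6-fold lower. The measured signal of Cd300lg fell by 6.65, that of Lfng, a glycosyltransferase that modifies Notch receptors, by 6.27 and that of Depp1 by 5.63 on the log2 scale, each with 1 of 4 inflamed arrays above background. That of the flavin monooxygenase Fmo2 fell by 6.52, of Pcp4l1 by 6.23 and of Tmem86a by 5.67, each with 2 of 4 inflamed arrays above background. The sizes of these falls rest in part on values under background. The epidermal keratins Krt10 and Krt2 were also among these 10: Krt10 fell by 5.99, with 1 of 4 inflamed arrays above background, and Krt2 was at least 11.6-fold lower.

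**Figure D1:**
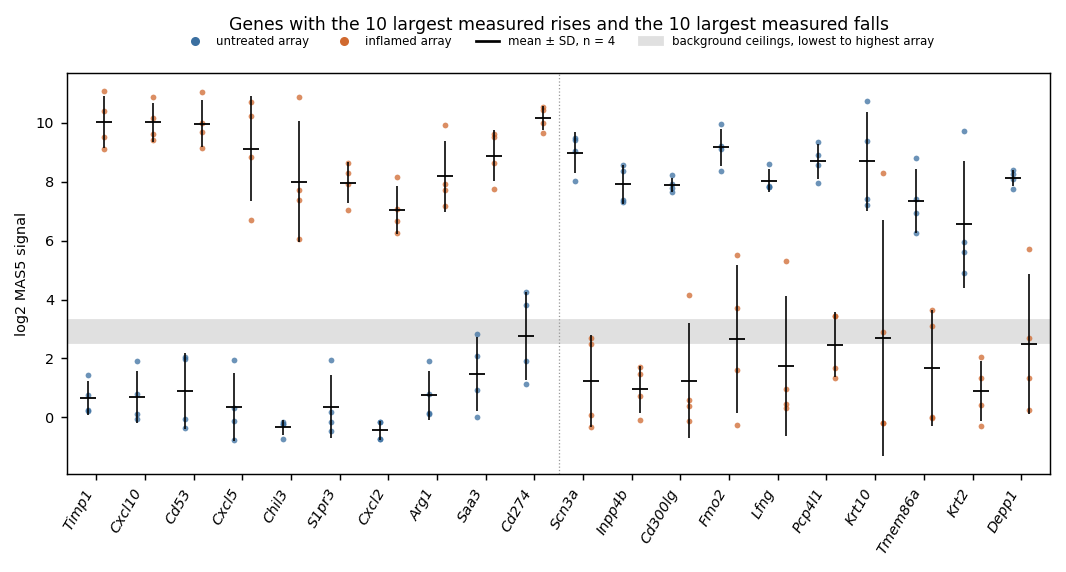
The vertical axis gives the log2 MAS5 signal of each array for the 10 genes with the largest measured rise (left of the dotted line) and the 10 with the largest measured fall (right), with points for arrays and bars for mean ± SD of 4 arrays per group. The grey band spans the background ceilings from 2.53 to 3.31. Timp1 lay under it on all 4 untreated arrays and averaged 10.03 on inflamed arrays.

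Chemokine genes rose as a group: 14 of 20 tested members were higher and 0 lower, or 15 adjusted over the list alone, with a median change of 5.02, or 3.85 with genes under background set to their bound (camera adjusted p = 1.61e-16; adjusted p = 0.059 with an estimated correlation). Beyond Cxcl10 and Cxcl5, Cxcl1 rose by 2.89 ± 0.19 (SE) and Ccl9 by 5.59 ± 0.54. The 5 tested neutrophil markers (mean log2 level 6.86 in inflamed against 1.89 in untreated samples) and the monocyte and macrophage markers (6.29 against 3.94) moved with this group. The untreated neutrophil mean lies under the background ceilings. Without the filter on dim probe sets, the median change of all 16 neutrophil markers on the array was 0.89. Of the 20 chemokines, 11 were higher without the intensity trend, and 7 of 9 tested with the stricter filter. Of the atypical receptors, which take up chemokines without G protein signalling, Ackr2 rose by 1.82 ± 0.29 and Ackr3 by 0.68 ± 0.15, while Ackr4 differed by -0.51 ± 0.25 and did not pass; this list of 3 tested genes was too short for the list test, and 0 passed without the intensity trend or without pair 3.

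Of 32 tested interferon-stimulated genes, 24 were higher and 0 lower, or 26 adjusted over the list alone (median change 3.27; camera adjusted p = 5.07e-29; adjusted p = 0.059 with an estimated correlation). The guanylate-binding proteins Gbp2, Gbp6 and Gbp3 rose by 5.87 ± 0.23, 5.87 ± 0.37 and 4.81 ± 0.36 (SE), and the interferon-inducible GTPase Iigp1 by 4.89 ± 0.32. Gbp2 had the smallest adjusted p of all genes, 6.94e-06. Of the 32, 16 were higher without the intensity trend. The 5 tested neutrophil markers, at 6.86 in inflamed against 1.89 in untreated samples, and the monocyte markers moved with the interferon-stimulated and the MHC class I genes. In MHC class I presentation, 14 of 17 members were higher and 0 lower, or all 17 adjusted over the list alone (median 2.37; camera adjusted p = 5.84e-20; adjusted p = 0.0632 with an estimated correlation). The immunoproteasome subunit Psmb8 rose by 6.63 ± 0.53 (3 of 4 untreated arrays above background), the peptide-loading protein Tapbp by 2.37 ± 0.16, B2m, the light chain of class I molecules, by 1.34 ± 0.09 and the heavy chain H2-K1 by 1.06 ± 0.11. Only 3 of the 17 were higher without the intensity trend. In MHC class II presentation, 2 of 9 members were higher, or 5 adjusted over the list alone (median 1.80; camera adjusted p = 0.00218; adjusted p = 0.161 with an estimated correlation). Those were the invariant chain Cd74, by 4.28 ± 0.95, and the protease Ctss, by 5.34 ± 1.20, each with 2 of 4 untreated arrays above background. H2-DMa at 3.52 ± 0.99 (1 of 4) and H2-Ab1 at 1.80 ± 0.55 did not pass. The count of class II genes was 4 under median centring and 0 without the intensity trend, without pair 1 or without pair 4. The monocyte and macrophage list, which also holds Ctss, moved with this group, at 6.29 in inflamed against 3.94 in untreated samples. The dendritic cell list stood at 6.77 against 5.17, but it holds Cd74 and H2-Aa, themselves class II genes, so its rise is no separate sign. Of its other tested members Irf8 rose by 3.07, while Epcam and Zbtb46, the latter named outside the rule, differed by -2.23 and -0.11.

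Of 24 tested NF-kB targets, 11 were higher and 0 lower, or 16 adjusted over the list alone (median 1.67; camera adjusted p = 9.86e-14; adjusted p = 0.059 with an estimated correlation). They included Ccl2, a chemoattractant of monocytes, by 5.71 ± 0.63 (SE), the transcription factor Irf1 by 2.83 ± 0.33 and the mitochondrial superoxide dismutase Sod2 by 2.27 ± 0.27. Cytokines and growth factors went both ways, with 6 of 26 higher and 3 lower, or 9 and 6 adjusted over the list alone (camera adjusted p = 0.0137, not under the stricter filter or without pair 2; adjusted p = 0.276 with an estimated correlation). Il1b was at least 24.96-fold and Il6 at least 12.04-fold higher, Csf1, a growth factor of macrophages, rose by 3.94 ± 0.61, and Tgfb3 fell by 1.78. Il1b is also a member of the neutrophil list, and the neutrophil and monocyte markers given above moved with the NF-kB and cytokine groups. Without the intensity trend 4 NF-kB targets were higher, and 2 cytokines were higher and 0 lower. Of 23 cytokine receptors and signalling inhibitors, 5 were higher and 0 lower, or 7 adjusted over the list alone (camera adjusted p = 0.00576; adjusted p = 0.134 with an estimated correlation). Among them were the feedback inhibitor Socs3 by 1.22 ± 0.18, Il17ra by 1.38 ± 0.24, Tnfrsf1a by 1.57 ± 0.32 and Il1r1 by 2.69 ± 0.55, whose call ended without the pair block. In this group 0 genes passed without the intensity trend.

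Of 15 leukocyte adhesion molecules, 3 were higher and 1 lower, with the same counts adjusted over the list alone (camera adjusted p = 0.0241, not under quantile or cyclic loess normalization or without pair 2; adjusted p = 0.384 with an estimated correlation). P-selectin, Selp, rose by 6.62 ± 0.80 (SE; 2 of 4 untreated arrays above background), the integrin ligand Icam1 by 1.53 ± 0.19 and the hyaluronan receptor Cd44 by 3.47 ± 0.73, while Cd99l2 fell by 3.00. The counts were 1 and 0 without the intensity trend. Vcam1 differed by 1.49 ± 0.62 and did not pass (adjusted p = 0.199). The chemokine Cxcl12 differed by 1.16 ± 0.50 and did not pass (adjusted p = 0.210). Of 16 genes of T cell regulatory ligands and enzymes, 7 were higher and 0 lower, or 8 adjusted over the list alone (camera adjusted p = 3.33e-07; adjusted p = 0.0632 with an estimated correlation). Besides Cd274 and Arg1, these included the galectin Lgals1 by 1.70 ± 0.24 and the prostaglandin synthase Ptgs2 by 6.07 ± 0.88 (1 of 4 untreated arrays above background). The neutrophil and monocyte markers moved with this group too. The count was 4 of 16 without the intensity trend and 4 of 9 tested with the stricter filter. Of 16 complement and coagulation genes, 6 were higher and 0 lower, or 8 and 1 adjusted over the list alone (camera adjusted p = 0.000241; adjusted p = 0.155 with an estimated correlation). Among these, the C1 inhibitor Serping1 rose by 2.87 ± 0.31, complement factor B, Cfb, by 2.90 ± 0.48, C1s1 by 3.08 ± 0.59 and thrombomodulin, Thbd, by 1.13 ± 0.20. The monocyte markers, and the fibroblast markers at a mean level of 8.06 in inflamed against 7.53 in untreated samples, moved with this group. Only 1 complement gene was higher without the intensity trend or without pair 3.

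Of 25 proteases and protease inhibitors, 9 were higher and 2 lower, or 9 and 3 adjusted over the list alone (camera adjusted p = 0.000386; adjusted p = 0.134 with an estimated correlation). Beside the inhibitor Timp1, the proteases Mmp3, Adamts4 and Adamts1 rose by 7.21 ± 0.77, 4.94 ± 0.46 and 1.77 ± 0.20 (SE), Mmp3 with 2 of 4 untreated arrays above background. Fibroblast markers moved with this group, at a mean level of 8.06 in inflamed against 7.53 in untreated samples. Some were bright in both groups. Col1a2 and Dcn, named outside the rule, averaged 11.8 and 11 in untreated and 12.04 and 11.91 in inflamed samples. Pecam1, the gene of the sort marker CD31, averaged 10.5 in untreated and 9.78 in inflamed samples. Others were dim, such as Col14a1, also outside the rule, at 2.86 and 4.07. Whether the rises in this group came from fibroblasts among the sorted cells was not tested. Basement membrane and matrix genes went both ways, with 3 of 23 higher and 4 lower, or 3 and 7 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.621). Tenascin C, Tnc, rose by 6.17 ± 0.51, Col4a1 by 1.45 ± 0.16 and Nid1 by 1.09 ± 0.19, and Fbln5 fell by 2.30. Without the intensity trend 4 proteases and inhibitors were higher and 1 lower, and 1 matrix gene was higher and 0 lower.

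**Figure D2:**
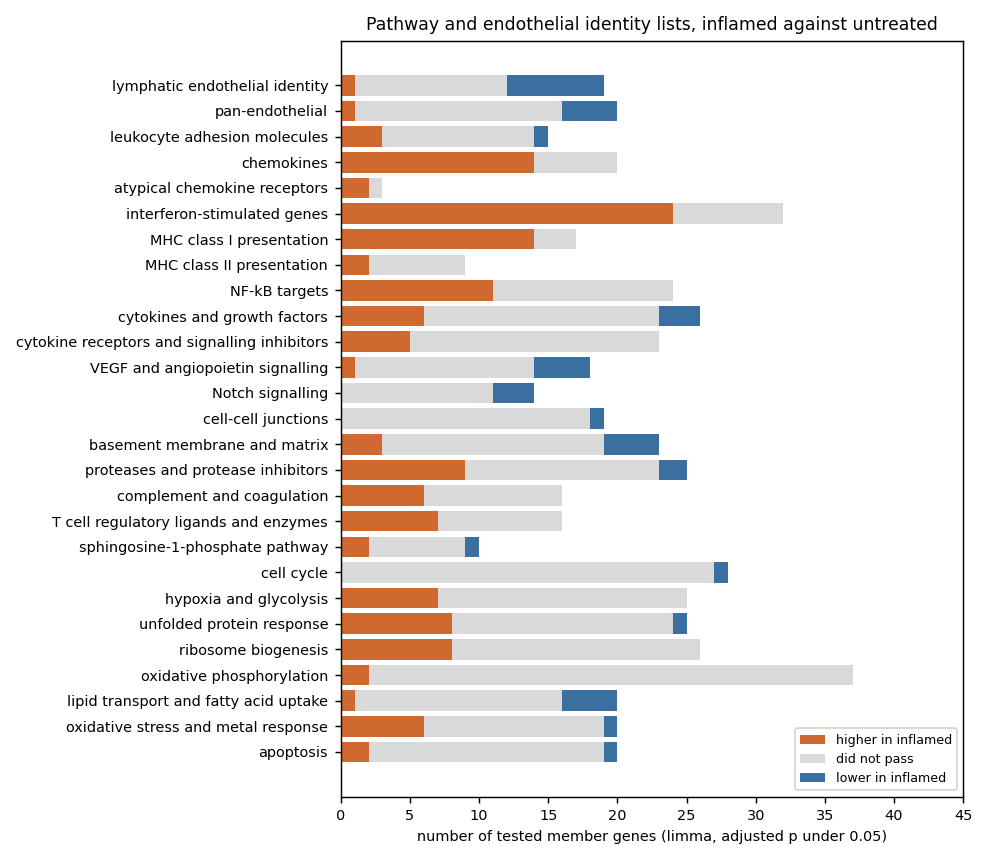
Horizontal bars give the number of tested member genes of each pathway and endothelial identity list that were higher (orange), lower (blue) or did not pass (grey) in inflamed against untreated samples at a limma adjusted p under 0.05. Of the interferon-stimulated genes, 24 of 32 were higher, and of the lymphatic endothelial identity genes 7 of 19 were lower.

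Of 19 tested lymphatic endothelial identity genes, 7 were lower and 1 higher, or 10 and 3 adjusted over the list alone (median change -0.46; camera adjusted p = 0.000323; adjusted p = 0.279 with an estimated correlation). The count of lower genes was 11 under quantile and cyclic loess normalization and 5 under median centring, and without the intensity trend 0 members of this list or of the pan-endothelial list passed in either direction. It was 4 without pair 1 or without pair 4. While the means of both lists fell in all 4 pairs, those of neutrophil (1.89 in untreated to 6.86 in inflamed samples), monocyte (3.94 to 6.29) and fibroblast markers (7.53 to 8.06) rose in all 4, and the 3' to 5' log2 ratio of Gapdh fell from 3.86 to 3.06. That of Actb was -0.08 in untreated and -0.07 in inflamed samples. The neutrophil mean covers the 5 of 16 markers that passed the filter on dim probe sets, and over all 16 the median change was 0.89. Multimerin 1, Mmrn1, fell by 1.20, Nrp2, a receptor for lymphangiogenic growth factors, by 1.72, Fxyd6 by 2.34 and the tight junction gene Cldn11 by 3.48 on the log2 scale. Of the lymphatic markers reported in any case, Lyve1, Flt4 and Prox1 did not pass (adjusted p = 0.467, 0.139 and 0.0618). Flt4 and Prox1 were nevertheless lower in all 4 pairs, and Lyve1 in 3. Lyve1 was 11.96 ± 0.31 in inflamed and 12.14 ± 0.26 in untreated samples (SD, n = 4), a difference whose sign turned under median centring, Flt4, the VEGF-C receptor, 11.93 ± 0.31 and 12.30 ± 0.17, and Prox1, the lymphatic master regulator, 9.74 ± 1.38 and 11.17 ± 0.18. Of 20 pan-endothelial genes, 4 were lower and 1 higher, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.0276, a call that ended without the pair block or with a random one, under median centring and without the intensity trend; adjusted p = 0.205 with an estimated correlation). The transcription factor Sox18 fell by 2.19, the VEGF receptor Kdr by 1.71 and the receptor Tie1 by 2.18, and Ecscr rose by 1.15 ± 0.19 (SE). Among 16 blood endothelial markers, 4 were lower and 1 higher, or 6 and 1 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.197). The carbonic anhydrase Car4 rose by 5.69 ± 0.67 (1 of 4 untreated arrays above background), and Aqp1, Efnb2 and Gpihbp1 fell by 1.63, 1.42 and 2.76, Gpihbp1 with 3 of 4 inflamed arrays above background. The call of Gpihbp1 ended without the pair block, and the calls of all 3 ended without the intensity trend.

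The genes used for the sort were as follows. Pecam1, which encodes CD31, was 9.78 ± 0.85 in inflamed and 10.50 ± 0.10 in untreated samples (SD, n = 4; adjusted p = 0.188), and Pdpn, podoplanin, was 12 ± 0.36 and 11.44 ± 0.44 (adjusted p = 0.0605). Ptprc, which encodes CD45 and served to exclude leukocytes, was too dim to be tested: it was above background on 0 untreated and 3 inflamed arrays, with signals of 28.2, 3.16, 8.27 and 35.3 on inflamed arrays 1 to 4.

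**Figure D3:**
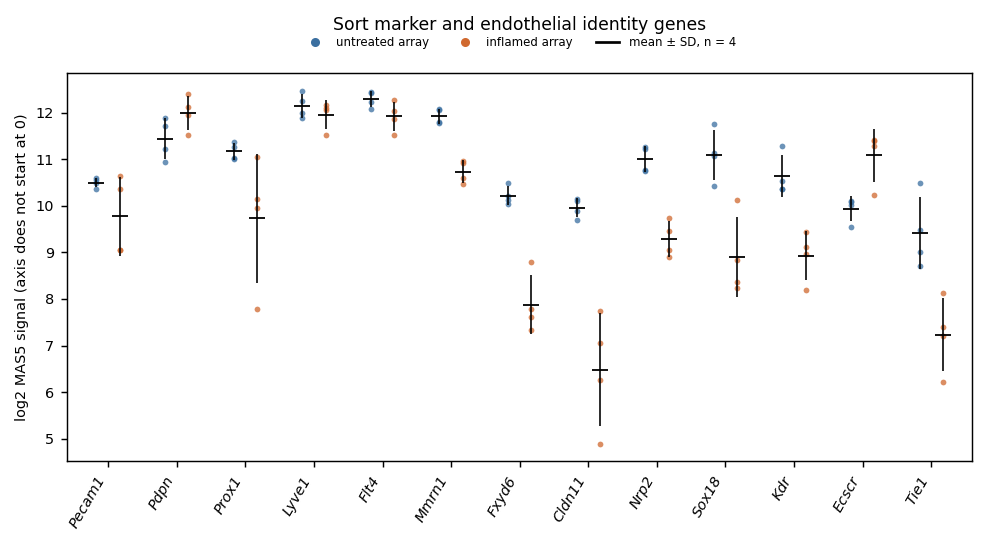
The vertical axis gives the log2 MAS5 signal per array of the sort marker genes and endothelial identity genes named in the text, with points for arrays and bars for mean ± SD of 4 arrays per group. Mmrn1, Fxyd6, Cldn11, Nrp2, Sox18, Kdr and Tie1 were lower in inflamed samples and Ecscr was higher, whereas Lyve1 stood at 11.96 in inflamed and 12.14 in untreated samples.

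Of 14 Notch pathway genes, 3 were lower and 0 higher, or 4 lower adjusted over the list alone (median change -1.08; camera adjusted p = 0.000775; adjusted p = 0.134 with an estimated correlation). Beside Lfng, the target gene Hey1 fell by 2.62 and the receptor Notch1 by 1.85, and the ligand Jag2 differed by -2.28 ± 0.70 (SE) without passing. Of 18 genes of VEGF and angiopoietin signalling, 4 were lower and 1 higher, or 5 and 3 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.401). The gene that rose was Angpt2, by 1.16 ± 0.26, a call that ended without the pair block and with a random one. Without the intensity trend 1 Notch gene was lower, and 0 genes of VEGF signalling, lipid transport or junctions passed. In lipid transport and fatty acid uptake, 4 of 20 genes were lower and 1 higher, with the same counts adjusted over the list alone, and the list did not pass (camera adjusted p = 0.197). The cholesterol exporters Abca1 and Abcg1 fell by 2.31 and 3.46, and the nuclear receptor Pparg fell by 2.05. Of 19 junction genes, 1 was lower, or 4 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.120, under 0.05 with quantile or cyclic loess normalization and without the filter). Gja1 at 0.63 ± 0.17, Gja4 at -1.82 ± 0.49 and Cldn5 at -0.66 ± 0.18 did not pass. In the sphingosine-1-phosphate pathway, 2 of 10 genes were higher and 1 lower, or 3 and 1 adjusted over the list alone (camera adjusted p = 0.165). Beside S1pr3, Plpp3 rose by 1.34 ± 0.31, the kinase Sphk2 fell by 2.04, and S1pr2 differed by 2.80 ± 0.94 (2 of 4 untreated arrays above background) without passing.

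Differences in metabolic and stress genes came with a 3' to 5' log2 ratio of Gapdh that fell from 3.86 in untreated to 3.06 in inflamed samples and a mean signal that rose from 135.4 to 147.5, each in all 4 pairs. Both Gapdh control signals rose, the 3' one from 2382 to 4914 and the 5' one from 162.2 to 631.4. The ratio of Actb was -0.08 in untreated and -0.07 in inflamed samples, so a general difference in RNA quality cannot be read from Gapdh alone. Of 26 ribosome biogenesis genes, 8 were higher and 0 lower, or 20 adjusted over the list alone (median 1.25; camera adjusted p = 5.53e-13; adjusted p = 0.059 with an estimated correlation). Noc4l rose by 2.25 ± 0.24, Fbl by 1.95 ± 0.30, Ncl by 1.07 ± 0.14 and Npm1 by 0.86 ± 0.10 (SE). The count was 14 under median centring and 0 without the intensity trend. Of 25 genes of the unfolded protein response, 8 were higher and 1 lower, or 11 and 1 adjusted over the list alone (camera adjusted p = 1.16e-06; adjusted p = 0.0632 with an estimated correlation). The endoplasmic reticulum chaperone Hspa5 rose by 1.24 ± 0.22, Dnajb11 by 1.20 ± 0.20, Manf by 1.92 ± 0.28 and Creld2 by 1.63 ± 0.28, and 0 passed without the intensity trend. Of 25 hypoxia and glycolysis genes, 7 were higher and 0 lower, or 10 adjusted over the list alone (camera adjusted p = 0.000147; adjusted p = 0.134 with an estimated correlation). Pfkfb3, an activator of glycolysis, rose by 3.90 ± 0.45, Hif1a by 1.94 ± 0.34, Ldha by 1.43 ± 0.18 and Pkm by 1.28 ± 0.24, with 1 higher gene left without the intensity trend and 2 without pair 3. Of 20 genes of the oxidative stress and metal response, 6 were higher and 1 lower, or 9 and 3 adjusted over the list alone (camera adjusted p = 0.000256; adjusted p = 0.0998 with an estimated correlation). The metallothioneins Mt2 and Mt1 rose by 4.88 ± 0.22 and 4.08 ± 0.28, and the zinc transporter Slc39a14 by 2.66 ± 0.27, with 3 higher and 0 lower without the intensity trend. Of 37 genes of oxidative phosphorylation, 2 were higher, the same count adjusted over the list alone, Cycs by 1.74 ± 0.23 and Ndufa5 by 0.59 ± 0.12. The call of Ndufa5 ended without the pair block and with a random one, and the count was 7 under median centring and 0 without the intensity trend. The list passed (camera adjusted p = 0.000874; adjusted p = 0.147 with an estimated correlation) but not under quantile or cyclic loess normalization.

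Among apoptosis genes 2 of 20 were higher and 1 lower, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.0524, under 0.05 in several alternatives, median centring among them). Bak1 rose by 2.68 ± 0.48 and Casp4 by 3.10 ± 0.56 (SE), Trp53inp1 fell by 2.22, and Cdkn1a at 1.69 ± 0.45 did not pass. Among apoptosis, cell cycle and reference genes, 0 passed without the intensity trend. Of 28 cell cycle genes, 1 was lower, Cdca8 by a change of -3.63 ± 0.92 (3 of 4 inflamed arrays above background), and 0 adjusted over the list alone (camera adjusted p = 0.649). Immediate early and dissociation stress genes, which cell isolation can induce, counted 3 of 28 higher and 1 lower, or 5 and 2 adjusted over the list alone (camera adjusted p = 0.490). Fosl2 rose by 2.06 ± 0.23, Ccn2 by 0.93 ± 0.16 and Fosl1 by 3.59 ± 0.75 (1 of 4 untreated arrays above background), and Btg2 fell by 2.20; the median of this list, -0.05, and its mean, 0.11, differ in sign. Of 12 reference genes, 3 were higher, or 5 adjusted over the list alone (camera adjusted p = 0.00429, not under quantile or cyclic loess normalization or without the intensity trend; adjusted p = 0.134 with an estimated correlation). These were B2m, Pgk1 by 1.01 ± 0.20 and Rpl13a by 0.39 ± 0.08, a call that ended without the pair block and with a random one, and Actb differed by 0.32 ± 0.10 without passing, with the opposite sign under cyclic loess normalization.

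Markers of other cell types differed between the groups as well. Of 5 tested neutrophil markers, 3 were higher, or 4 adjusted over the list alone (camera adjusted p = 4.41e-05, and adjusted p = 0.0982 with an estimated correlation): S100a9 rose by 7.30 ± 0.79, S100a8 by 7.02 ± 0.81 (SE), each with 1 of 4 untreated arrays above background, and Il1b as above. The other neutrophil markers on the array were too dim to be tested. Without the filter on dim probe sets, 3 of 16 were higher and the median change was 0.89, against 6.75 for the tested 5. Of 15 monocyte and macrophage markers, 3 were higher, or 5 adjusted over the list alone (camera adjusted p = 4.96e-05; adjusted p = 0.179 with an estimated correlation): Ctss, Fcer1g by 4.86 ± 0.95 (1 of 4 untreated arrays above background) and Aif1 by 3.54 ± 0.84 (2 of 4). The call of Aif1 ended without the pair block and with a random one, and 0 of this list passed without the intensity trend, without pair 1 or without pair 4. Of 5 dendritic cell markers, 2 were higher, or 3 adjusted over the list alone (camera adjusted p = 0.0395, not under median centring, without the filter, without the intensity trend or without pair 2; adjusted p = 0.290 with an estimated correlation): Irf8, an interferon-regulatory factor, by 3.07 ± 0.43, and Cd74. Of 19 fibroblast markers, 2 were higher, with the same count adjusted over the list alone (camera adjusted p = 0.00576, not without pair 3; adjusted p = 0.342 with an estimated correlation): Lum by 1.49 ± 0.29 and Col6a3 by 1.78 ± 0.45. Both calls ended without the pair block, with a random one, without the intensity trend, without pair 1 and without pair 3. Of 14 keratinocyte markers, 4 were lower, or 5 adjusted over the list alone (camera adjusted p = 0.0103; adjusted p = 0.412 with an estimated correlation): Krt2, Krt10, Krt15, at least 9.99-fold, and Krt5, which fell by 3.53 with 3 of 4 inflamed arrays above background. The keratinocyte list lost its call without pair 1 or pair 3, and 2 members were lower without the intensity trend. Of 7 pan-leukocyte and T cell markers, 0 passed (camera adjusted p = 0.772, and the median, -0.48, and the mean, 0.15, differ in sign), with Thy1 at -0.65 ± 0.19 and Coro1a at 2.77 ± 0.87 (3 of 4 untreated arrays above background). Thy1 averaged 11.18 in untreated samples, where Ptprc was above background on 0 arrays, so its change cannot be read as one of T cells. Of 3 mast cell markers, Hdc, the histamine-forming enzyme, rose by 6.11 ± 0.83 (1 of 4 untreated arrays above background). The other tested mast cell markers, Tpsb2 at 0.54 ± 0.78 and Gata2 at -0.06 ± 0.28, did not pass. Without the filter on dim probe sets the median change of the mast cell list was -0.425, against 0.537 for the tested 3. Among 6 pericyte and smooth muscle markers, Mylk fell by 1.25 (camera adjusted p of the list = 0.404). In the lists of chondrocytes (12 tested genes), skeletal muscle (7), Schwann cells (5), adipocytes (4) and B cells (1), 0 members passed.

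**Figure D4:**
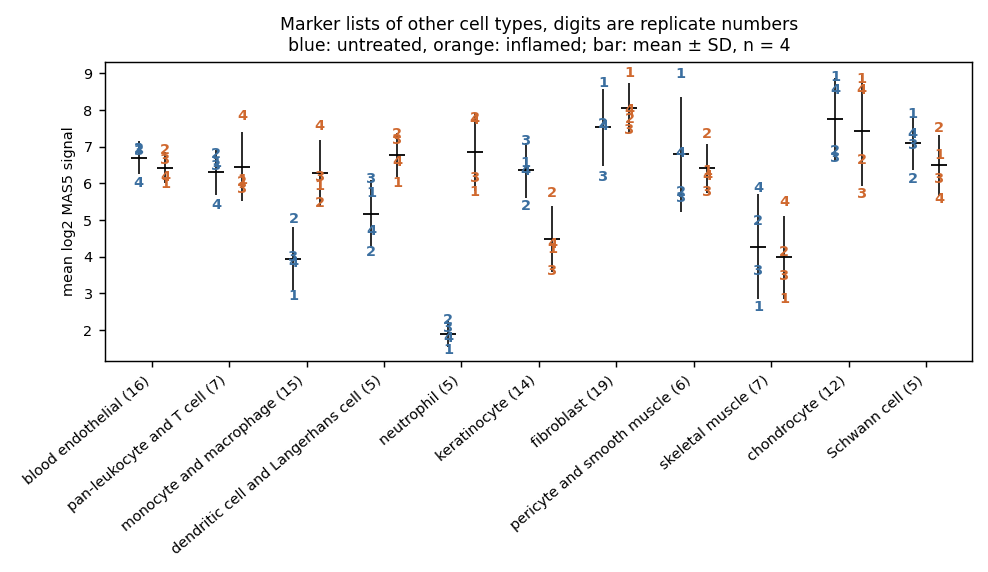
The vertical axis gives the mean log2 MAS5 signal of the tested members (their number in parentheses) of each marker list on each array, with digits for the replicate number, blue for untreated, orange for inflamed and bars for mean ± SD of 4 arrays. All inflamed arrays exceeded all untreated arrays for neutrophil markers, and chondrocyte markers stood at 8.89 and 8.86 on the arrays of pair 1 against 6.68 and 5.71 on those of pair 3.

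Array measures that bear on RNA quality were compared last. The 3' to 5' log2 ratio of the Gapdh control probe sets was 3.06 ± 0.33 in inflamed and 3.86 ± 0.34 in untreated samples (SD, n = 4), lower in all 4 pairs, the most extreme outcome of the exact sign-flip permutation, which 4 pairs cannot bring under 0.05. That of Actb was -0.07 ± 0.05 and -0.08 ± 0.06 (exact sign-flip permutation p = 0.75). The median log2 signal of all probe sets was 3.38 ± 0.08 in inflamed and 3.69 ± 0.09 in untreated samples, lower in all 4 pairs. The first principal component held 31.2% of the variance and separated the groups, and the second held 15%.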

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

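All tests of explanations in this part were chosen after the results were seen. A sample was looked at again where its gap to the nearest other sample of its group of 4 was, as a share of the group's range, above the 95% critical value of Dixon's test. Of 434 groups of 4 arrays examined, 20 had such a sample, against 21.7 by chance alone, so the individual cases below are of the number chance gives.

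Untreated array 1 stood apart for Ecscr (log2 signal 9.54 against a mean of 10.07 on the others), Ptgs2 (4.71 against -0.40), Acta2 (9.03 against 4.78), Hapln1 (8.44 against 6.86), the pan-endothelial list (mean 8.46 against 9.35) and the Notch list (7.28 against 7.14). Untreated array 4 stood apart for Lfng (8.62 against 7.83), Car4 (3.81 against 2.12), S100a9 (-0.0274 against 3.03) and the blood endothelial list (6.02 against 6.92). Untreated array 2 had a median log2 signal of 3.56 against 3.73. Inflamed array 1 stood apart for Ecscr (10.24 against 11.37), Efnb2 (8.21 against 9.11) and Fbln5 (6.28 against 7.58), and inflamed array 3 for Gja1 (11.34 against 11.94), Plin4 (4.79 against 1.33) and the immediate early list (9.31 against 9.90). Inflamed array 2 had Rgs5 at 5.70 against 2.20. Inflamed array 4 had Lfng at 5.30 against 0.57 and the pan-leukocyte and T cell list at 7.84 against 5.997.

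Among the 2893 tested probe sets with several genes or none, which the gene counts leave out, 150 changed between the groups, 99 higher and 51 lower in inflamed samples. Their genes were not named here.

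Myeloid transcripts were higher in inflamed samples: 6 members of the neutrophil and monocyte lists were called, namely S100a8, S100a9, Il1b, Fcer1g, Aif1 and Ctss. Scaling of the arrays by the authors is argued against as the source for these 6. Their measured changes, 3.54 to 7.30, far exceed the group difference of the array medians, -0.30. All 6 also kept direction and call under quantile, cyclic loess and median scaling, although the calls had chosen them, so little weight rests on this. Only the first 3 kept the call without the intensity trend. Leukocytes carried through the sort, which excluded cells with CD45, stay open: over the 17 tested list members in no pathway list, called or not, the median change was 3.75, 1.43, 2.82 and 3.46 in pairs 1 to 4 and 2.87 on average, which expression by the sorted cells would give too. These members had passed the filter on dim probe sets, which a gene dim in untreated samples passes more readily if it rose. Without that filter the median change was 0.89 over 16 neutrophil and 1.9 over 24 monocyte markers. A first form of this test, over members that were not called, was dropped because the calls had chosen its members. The abundant myeloid transcript Lyz2, chosen after its values were seen, had signals of 175, 42.1, 371 and 237 on inflamed arrays against 39.3, 48.5, 96.5 and 16.4 on untreated arrays. Expression by the inflamed endothelial cells themselves was not tested and stays open as well.

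Endothelial identity genes were lower in inflamed samples, 11 of the 39 tested members of the lymphatic and pan-endothelial lists, with 2 higher, although 0 in either direction passed without the intensity trend. A smaller share of endothelial cells among the sorted cells stays open as a cause. The members did not change by a common amount: 20 of the 39 had a 95% interval that excluded -0.65, the median change of all 39, against 1.95 by chance. Of these intervals, which use the moderated standard errors, 12 lay above it and 8 below. A smaller share would lower all members alike only if no other sorted cell expressed them, which was not tested. The means of the tested neutrophil (by 4.97 ± 0.91, SD over pairs), monocyte (2.35 ± 1.42) and fibroblast markers (0.53 ± 0.53) rose in all 4 pairs. Ptprc was measured higher in all 4 but was above background on only 3 inflamed arrays. In pair 2 both of its values lay under background, where no order can be read. It did not pass in limma without the filter on dim probe sets (adjusted p = 0.167). The sizes of these rises cannot show whether all other cells rose alike. The neutrophil mean rests on the 5 of 16 markers that passed the filter on dim probe sets. Its untreated level lies under the background ceilings, and over all 16 the median change was 0.89. A larger share of the cells that rose stays open as well. Scaling stays open in part: all 11 kept their direction under the 3 other scalings and 8 kept the call; of genes named only because they lost it, Itga9 (-1.43 before, -1.13 after), Reln (-0.91, -0.61) and Tek (-1.47, -1.16) did so under median centring, which moves each change by about the shift of the array medians. A change of expression with inflammation is the explanation the design offers and could not be tested apart from the groups.

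Chondrocyte marker levels lay close within pairs, which was noticed in the values first. Of the 24 ways to match untreated with inflamed arrays, the stated pairing gave the closest chondrocyte levels (1 of 24), but the list was picked for this closeness, so the count is a description and no test of it. The levels were 8.89 and 8.86 in pair 1, 6.87 and 6.64 in pair 2, 6.68 and 5.71 in pair 3 and 8.54 and 8.53 in pair 4, and Acan, chosen after its values were seen, had signals of 1990 and 2000 in pair 1 and 289 and 243 in pair 3. The stated pairing was also the closest for 5 other lists, 6 of 39 in all against 1.62 by chance, so a shared-day effect on genes in general stays open. Cartilage cells or RNA carried over on a shared day may also account for it and stay open, although the gate, which required CD31 and podoplanin, selects against such cells. The samples of a pair also shared their age, 9 weeks in pair 1, 8 in pairs 2 and 3 and 10 in pair 4. Day and age therefore cannot be told apart here.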

How the results depend on the processing

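The exact permutation of list means was chosen after the data were seen. In every alternative tested per gene, all genes shared with the reported calls kept their direction, for example 613 without the replicate block, which gave 384 higher and 301 lower genes, and no call reversed. Signs of values that had not passed did turn in at least 1 alternative for 10 examined genes, among them Lyve1 under median centring and Actb under cyclic loess, and for the medians of 13 lists, 7 of them under median centring, such as the VEGF list (-0.26 to 0.05) and the basement membrane list (-0.12 to 0.18). The fit without the block changed the calls of 8 named genes from passing to not passing and of 2 the other way, and ended 1 list call. Counts of higher genes moved by over 1.5 times under median centring (719), without the intensity trend (94) and per probe set (715), and counts of lower genes without the trend (47) and per probe set (545). Per probe set, more features than genes are tested; for the trend the cause was not tested, and median centring shifts all changes upward. Without one pair at a time, with fewer samples, 194 to 293 genes were higher and 103 to 185 lower. With an estimated correlation camera called 0 lists higher and 0 lower at an adjusted p under 0.05, against 21 and 4 with the preset one, while 14 had an unadjusted p under 0.05 and fry called 20 in all, 2 of them lower. Fry, which does not compare a list with other genes, did not call 7 of the 25: lymphatic endothelial identity (adjusted p = 0.053), adhesion (0.0686), cytokines (0.0686), monocyte (0.0698), dendritic cell (0.0551), keratinocyte (0.163) and fibroblast markers (0.163). The exact permutation over 35 splits, with a smallest possible p of 0.0286, called 0 higher and 0 lower after adjustment, although the real split was the most extreme for 20 lists. Signal over background limits 25 called genes with no untreated and 10 with no inflamed array above background, whose folds are bounds. Of 417 called genes with over 1 probe set, 380 had all of them in 1 direction.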

Other observations

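The tests of other splits were chosen after the results were seen. Whether chance alone could give as many calls was examined with other splits of the 8 arrays into 4 and 4. Without the pair block, the real split called 685 genes and the highest of the other splits 2, so that 1 of 35 splits gave as many. Chance is excluded at 0.05 for this unpaired fit only, which takes the arrays as exchangeable across the stated pairs. With the block, the real split called 752 genes and the highest other 0; 1 of the 8 splits that part every pair gave as many, and 8 splits are too few for a share under 0.05. For gene lists called by camera with the preset correlation, 2 of 35 splits gave as many as the real 24, and the highest other gave 25, so chance is not excluded for the number of lists. With the block, the real split called 25 lists and the highest other 18, 1 of 8 splits, too few for a share under 0.05. The number of lists called by camera therefore carries less weight than the gene counts, and the adjusted p with an estimated correlation stands beside each called list for that reason.

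Keratinocyte markers, of which 4 were called lower, were not lower in every pair: the mean level of the 14 tested members was 4.22 on the inflamed and 6.55 on the untreated array of pair 1, 5.73 and 5.37 in pair 2, 3.61 and 7.16 in pair 3 and 4.34 and 6.33 in pair 4 (exact sign-flip permutation p = 0.25).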
